A study of Arabidopsis thaliana with 12 samples.

How the data were processed

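RNA-seq was done on aerial parts of plants 6 days old, grown on medium with 1% sucrose under 16 h light and 8 h dark at about 21 °C after 3 days at 4 °C, per the labels' protocols. Per the labels, the mRNA libraries used a stranded mRNA kit and the total RNA libraries a stranded Ribo-Zero plant kit. The submitters' processing notes name FastQC 0.11.5, Bowtie2 2.2.9, edgeR 3.20.1 and TAIR10, with no roles or parameters, and neither they nor the labels give the counting tool or its strand setting. The values analysed were the deposited raw counts per gene, whole numbers for 33602 genes. The authors also deposited group means of normalized counts (a score rounded to whole numbers where a gene passed their filter), log2 fold changes and p-values with adjusted p-values, per the file headers.

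Groups came from the labels, whose titles name the wild type of the mRNA libraries 1171WTCol3 and that of the total RNA libraries WTCol0, with no word on the difference. The headers of 2 of the 3 columns used for tfIIfα1 name the other allele, but carry the run prefix that only the titles of the mRNA libraries have, and no title for tfIIfα2 has it. They end in 1 and 3, and the remaining column ends in 1 too, so the endings do not tell which is replicate 2 or 3. They were taken as tfIIfα1 replicates a and b, and their group rests on that prefix. The deposited tfIIfα1 mean equals a weighted sum of these 3 columns within 0.147%. A further 6 count columns belong to no sample of the series and were not used, and neither were 18 normalized columns per library. Gene symbols and descriptions came from the deposited table. The TAIR10.1 annotation served only for gene order, exon number, length and GC content, with 32835 genes matched, and no coordinates are given because the authors' build was TAIR10.

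Depth was 55915638 to 66711096 counts per mRNA library and 33292996 to 37456773 per total RNA library. Of the genes' counts, 57.6% to 61.5% were even in 4 mRNA libraries, 72.2% and 69.5% in tfIIfα1 replicates a and b, and 47.7% to 48.1% in the total RNA libraries. Why a and b stand apart was not tested. No replicate pair agreed within sampling noise (chi-square per degree of freedom from 10.1 to 49.8).

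Each allele was compared with the wild type of its kit in edgeR 4.0.16 (R 4.3.3) with filterByExpr, TMM normalization and the quasi-likelihood test, with Benjamini-Hochberg adjustment and a threshold of 0.05. The biological coefficient of variation was 0.0827 in the mRNA and 0.184 in the total RNA comparison. Standard errors are the absolute log2 fold change over the square root of the F statistic. CPM used TMM library sizes. The difference between the alleles was the interaction in a fit over 12 libraries, with 1 spread per gene for both kits. Gene lists, 25 with at least 3 tested members, were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and again with an estimated one, adjusted over the 25 lists. The lists, tests and named-gene rule were fixed before the data were examined. The lists cover the topoisomerase VI complex, basal transcription, PPR genes (all, plastid and mitochondrial editing), other editing factors, plastid transcription, nuclear photosynthesis, chlorophyll synthesis, mitochondrial stress, reactive oxygen, DNA damage, the cell cycle, brassinosteroids, the clock, heat shock, defense, flavonoids, seed reserves, root markers, organelle-encoded genes and ribosomal proteins. Of 320 hand-listed genes, 1 was dropped because the deposited description contradicted its list. The list of all PPR genes held those whose deposited name or description contains PPR or pentatricopeptide.

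Named genes were RAP74 and the topoisomerase VI genes, the 8 largest rises and 8 largest falls that passed with a mean of at least 1 CPM and no overlap between groups, up to 4 members per list by smallest p, the 6 largest shared rises and falls, and the 4 interaction genes with the smallest p. About 10% of unchanged genes would have groups of 3 against 3 apart by chance, and 49.4% and 28.7% of the tested genes did in tfIIfα1 and tfIIfα2.

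The pairing of the total RNA samples was inferred from the replicate numbers in their titles. Same-numbered libraries deviated together from their group means, with correlations of 0.78, 0.26 and 0.62 over genes, and each library correlated best with its own number. A fit with the number as a block is given where it changes a call or a count. For tfIIfα1 no such fit was run because the replicate numbers of 2 of its 3 columns are ambiguous.

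The pipeline was tested on simulated data with 200 genes changed by known folds. At 1.5-, 2- and 4-fold it recovered 72.7%, 88.1% and 98.4% in the tfIIfα1 comparison (20207 genes), 10.4%, 44.6% and 92.3% in the tfIIfα2 comparison (18707 genes), and 7.46%, 41.8% and 90.9% in the interaction (18477 genes). Alternatives were RLE normalization, other count filters, organelle genes removed, DESeq2 1.42.0, limma-voom, 1 fit over 12 libraries, stricter thresholds, each library left out, the block and random lists matched on expression (10000 per list, in 20 bins). Halved and thinned mRNA counts, removal of the chromosome 4 block and a list of PCMP symbols were added after the data were seen. The chromosome 4 block was the longest run of a running median over 11 genes below -0.5. In the authors' deposited table, 2058 genes were higher and 2099 lower at an adjusted p under 0.05 in tfIIfα1, and 1473 and 1427 in tfIIfα2. Its log2 fold changes correlate across genes with those computed here at r = 1.00 in both. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.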

Results

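RNA from the aerial parts of Arabidopsis thaliana plants 6 days old was sequenced in 12 libraries, 3 in each of 4 groups. Wild type and the mutant tfIIfα1 were prepared with a stranded mRNA kit, and wild type and the mutant tfIIfα2 with a stranded total RNA kit that removes ribosomal RNA. The titles name the wild type 1171WTCol3 in the mRNA and WTCol0 in the total RNA libraries. Both mutants carry alleles of the gene for the alpha subunit of TFIIF, a general factor that RNA polymerase II needs to start transcription. The title of the series joins this factor with topoisomerase VI and with PPR genes, whose proteins bind RNA in chloroplasts and mitochondria. Each mutant was compared with the wild type of its own kit, so differences between the alleles cannot be told apart from differences between the kits or their wild types. The mRNA libraries held 55915638 to 66711096 counts, and the total RNA libraries 33292996 to 37456773. Plastid-encoded genes took 57.3% to 62.5% of the total RNA counts, which left 12069295 to 14652749 counts on nuclear genes. The labels do not say that replicates were separate cultures, so p-values measure only the spread between these samples.

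The targeted gene, RAP74 (AT4G12610), was lower in each mutant library than in each wild-type library of its kit. In the mRNA libraries its level was 21.3, 21.2 and 18.4 CPM in wild type and 14.3, 16.5 and 15.9 CPM in tfIIfα1 (log2 fold change -0.38 ± 0.08 SE, adjusted p = 0.0022, edgeR). In the total RNA libraries it was 8.06, 7.58 and 8.06 CPM in wild type and 4.84, 6.03 and 5.78 CPM in tfIIfα2 (log2 fold change -0.51 ± 0.12 SE). This second difference had an adjusted p of 0.066 in edgeR, and of 0.017 with the replicate number as a block. Reads over RAP74 do not show where the mutations lie, so they check the labels only as far as a lower level can.

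**Figure D1:**
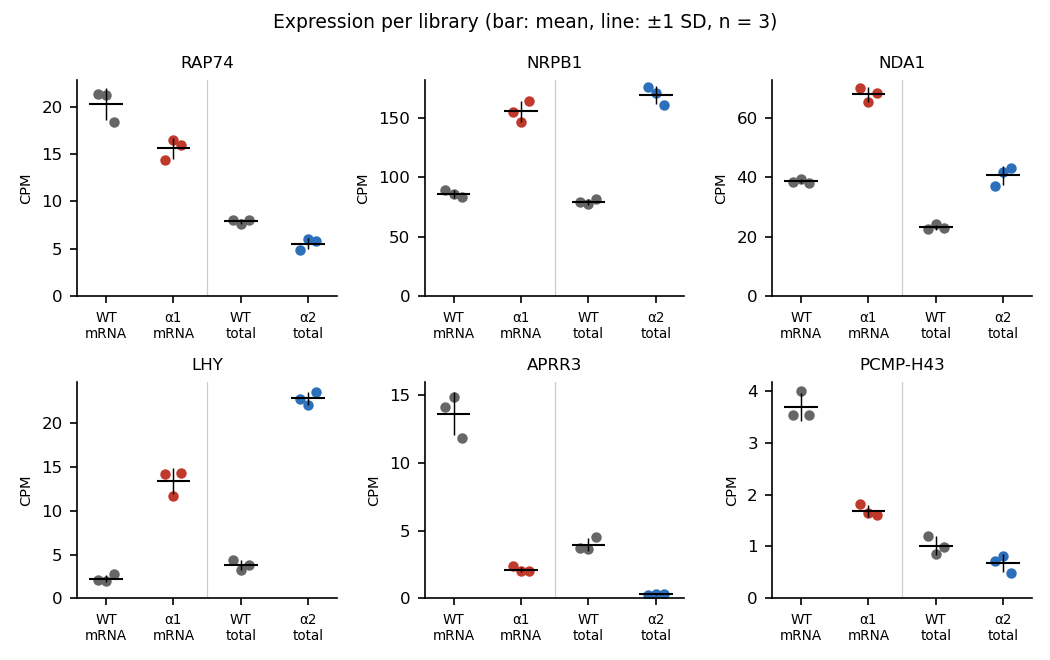
Expression (CPM, linear axes from 0) of 6 genes in each library of the 4 groups, with the mean and ±1 SD of 3 libraries. RAP74, APRR3 and PCMP-H43 had lower means in the mutants, and NRPB1, NDA1 and LHY higher means, in both kits.

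The first comparison asked which transcripts differed in tfIIfα1 against wild type in the mRNA libraries. Of 29 PPR genes for mitochondrial RNA editing 23 fell in tfIIfα1, with a median log2 fold change of -0.94. Of 13 genes of mitochondrial stress 6 rose, among them UGT74E2, a glycosyltransferase gene (37.6-fold), and HSP23.5, a small heat shock protein of mitochondria (4.36-fold). Of 16 genes of basal transcription 8 rose, among them NRPB1, the largest subunit of RNA polymerase II (1.81-fold), and 1 fell, though the list had adjusted p = 0.251 with an estimated correlation. The morning clock gene LHY was 5.90-fold higher, and the evening-side genes ADO3 and APRR3 were 4.29-fold and 6.41-fold lower. Of 20371 genes tested, 7820 changed (38.4%), 3818 higher and 4002 lower, and 446 of the higher and 623 of the lower ones changed at least 2-fold.

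Among the 8 largest rises in tfIIfα1 were 3 plant defensin genes, PDF1.2B (log2 fold change 5.42 ± 0.52), PDF1.3 (4.27 ± 0.40) and PDF1.2A (3.75 ± 0.42). UGT74E2 rose by 5.23 ± 0.31 from 0.400 ± 0.190 to 15.2 ± 5.37 CPM (SD, n = 3), and the transporter gene DTXL1 by 4.67 ± 0.35. ACT, an anthocyanin acyltransferase gene, rose by 4.42 ± 0.36, SEC31A by 3.93 ± 0.27 and AT2G18193 by 3.86 ± 0.27. Among the 8 largest falls, AT5G03545 fell by 3.34 ± 0.41, AT4G04409 by 2.75 ± 0.27, and APRR3 fell by 2.68 ± 0.12. BGLU43, a beta-glucosidase gene, was among them at -2.71 ± 0.26. The other largest falls, DL3625W (-3.26 ± 0.36), ABCG30 (-2.96 ± 0.17), PCMP-H13 (-2.67 ± 0.24) and AT4G13800 (-2.57 ± 0.12), lie in a block of chromosome 4 described next. All of these genes had an adjusted p of 2.1e-05 or less in edgeR, and their mutant and wild-type libraries did not overlap. Defensin genes share reads with near-identical copies, so their separate values are uncertain.

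A single block of neighbouring genes on chromosome 4, from AT4G12640 to UGT75D1 (AT4G15550), was lower in tfIIfα1. It held 399 genes, began 1 tested gene after RAP74, and had a median log2 fold change of -0.996 over 270 tested genes, of which 233 fell and 4 rose. The 100 tested genes before it and the 100 after it had medians of -0.01 and 0.00. In tfIIfα2 the same block had a median of -0.03 over 239 tested genes, with 5 lower and 4 higher. Across kits, the block genes lay 0.98 above the other chromosome 4 genes in wild-type mRNA against wild-type total RNA libraries (log2, bootstrap interval 0.88 to 1.11), and -0.01 in tfIIfα1 against tfIIfα2 (-0.13 to 0.09). The offset lay in the wild-type mRNA libraries, and values of block genes in tfIIfα1 carry it. All other tfIIfα1 changes were measured against the same libraries. Any further difference of that wild-type line cannot be told apart from the mutation. The block was found after the values were seen.

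**Figure D2:**
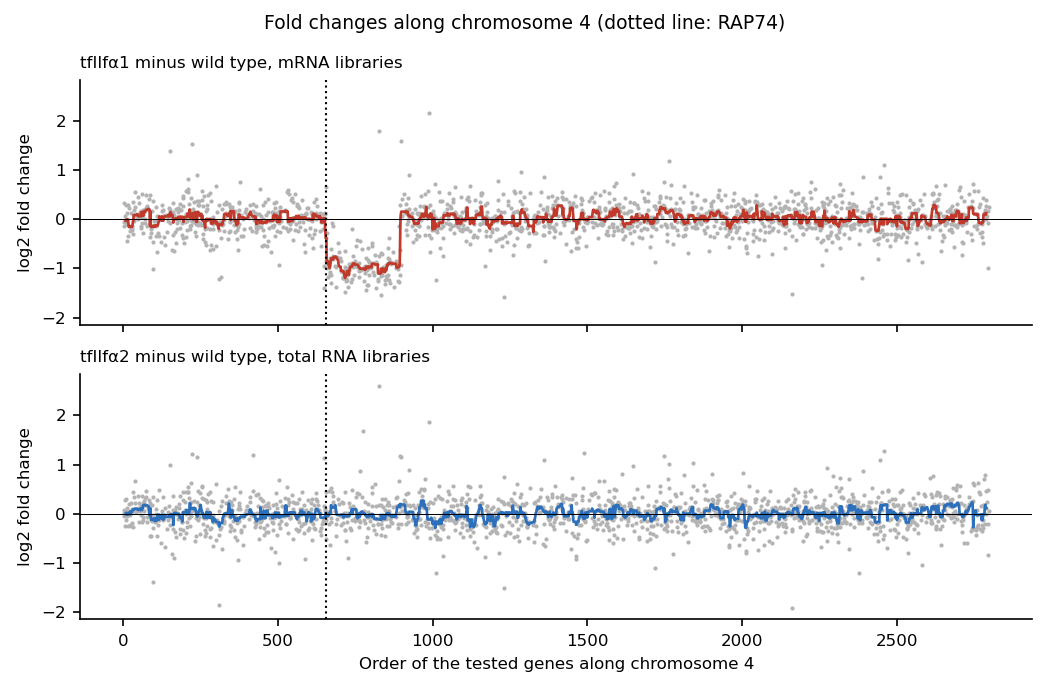
Log2 fold changes of genes along chromosome 4, in gene order, in tfIIfα1 (mRNA libraries) and tfIIfα2 (total RNA libraries). Points are genes with a log2 CPM over 2 in both comparisons, lines are running medians over 11 genes, and the dotted line is RAP74. The median of the block after RAP74 was -0.996 in tfIIfα1 and -0.03 in tfIIfα2.

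Of 247 PPR genes tested in tfIIfα1, 109 fell and 28 rose (113 and 29 adjusted over the list alone), with a median of -0.30 (camera adjusted p = 3.4e-05). Their call ended with adjusted p = 0.251 with an estimated correlation. The list leaves out 96 tested genes with a PCMP symbol, a name given mostly to PPR proteins with E or DYW domains. Of these, 66 fell and 4 rose, with a median of -0.88. Of the 159 listed genes without a PCMP symbol and in neither editing list, 39 fell and 25 rose, with a median of -0.06. Of the 84 listed genes with such a symbol, 68 fell and 2 rose, with a median of -0.91, so they carry most of the decrease. Both sets were made after the data were seen. The title of the series names PPR genes, so the study may have chosen them on these samples. The list is therefore not taken as independent evidence of its direction. With the chromosome 4 block genes left out of the fit, 102 of 240 PPR genes fell and 26 rose. The 4 PPR genes with the smallest p, PCMP-H42 (-1.58 ± 0.10), LOI1 (-1.59 ± 0.11), AT4G14190 (-1.09 ± 0.09) and AT4G14200 (-0.94 ± 0.08), all lie in the block. Of 29 PPR genes for mitochondrial editing, 23 fell and 1 rose (the same counts adjusted over the list alone, camera adjusted p = 1.6e-08). That call had adjusted p = 0.0565 with an estimated correlation, and the study's possible choice of PPR genes on these samples limits it too. Without the block, 20 of 26 fell and 1 rose, with a median of -0.92. LOI1 and PCMP-H13 lie in the block, and PCMP-H43 (-1.12 ± 0.15, adjusted p = 5.3e-05 in edgeR) does not. Of 19 PPR genes for plastid editing, 8 fell and 2 rose (camera adjusted p = 0.239). DYW1 (0.78 ± 0.07) and CRR21 (0.48 ± 0.06) rose, and PCMP-H33 (-0.76 ± 0.10) and PDE247 (-0.89 ± 0.12) fell.

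Editing factors that are not PPR proteins moved the other way, with 9 of 15 higher and 0 lower (camera adjusted p = 0.0121, adjusted p = 0.686 with an estimated correlation). MORF4 rose by 0.91 ± 0.13, MORF5 by 0.44 ± 0.07, MORF3 by 0.37 ± 0.08 and RBG3 by 0.57 ± 0.11. Of 16 genes of basal transcription, 8 rose and 1 fell (camera adjusted p = 0.0012, adjusted p = 0.251 with an estimated correlation). NRPB1 rose from 86.0 ± 3.29 to 155 ± 8.81 CPM (0.85 ± 0.06), the initiation factor gene TFIIB1 by 0.81 ± 0.06, NRPB2 by 0.55 ± 0.06 and TAF1 by 0.43 ± 0.06. Of the topoisomerase VI genes, TOP6B rose by 0.31 ± 0.09 (adjusted p = 0.013 in edgeR). TOP6A (0.12 ± 0.08), RHL1 (0.15 ± 0.10) and BIN4 (-0.13 ± 0.12) did not pass, and the list was not called (camera adjusted p = 0.637).

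Of 13 genes of mitochondrial stress, 6 rose and 0 fell (camera adjusted p = 4.8e-06, adjusted p = 0.0765 with an estimated correlation), with NDA1, an alternative NADH dehydrogenase gene, at 0.81 ± 0.06 and HSP23.5 at 2.12 ± 0.22. Of 15 DNA damage genes, 9 rose and 0 fell (camera adjusted p = 0.0017, adjusted p = 0.287 with an estimated correlation), with anac044 at 2.01 ± 0.21, GMI1 at 1.07 ± 0.14 and RAD17 at 0.73 ± 0.11. Of 12 genes of singlet oxygen and reactive oxygen, 4 rose and 1 fell (camera adjusted p = 0.0121, adjusted p = 0.251 with an estimated correlation), with the catalase gene CAT2 at 0.86 ± 0.06 and CSD2, a superoxide dismutase gene, at 1.03 ± 0.16. Of 12 chlorophyll synthesis genes, 9 rose and 1 fell (camera adjusted p = 0.000255, adjusted p = 0.108 with an estimated correlation). PORA, a protochlorophyllide reductase gene, rose by 2.09 ± 0.17, CRD1 by 0.60 ± 0.05 and PORC by 0.57 ± 0.06, and PORB fell by 0.50 ± 0.06.

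Clock genes moved in both directions in tfIIfα1, with 4 of 12 higher and 8 lower (camera adjusted p = 0.0255, adjusted p = 0.614 with an estimated correlation). LHY rose by 2.56 ± 0.13 and CCA1 by 1.01 ± 0.10, and ADO3 was 4.29-fold lower and APRR1 fell by 1.34 ± 0.09. Of 11 flavonoid genes, 3 rose and 0 fell (camera adjusted p = 0.0368, adjusted p = 0.686 with an estimated correlation), among them CHS, the first enzyme of the pathway, at 1.04 ± 0.11 and F3H at 0.81 ± 0.13. Of 351 ribosomal protein genes, 180 rose and 37 fell (camera adjusted p = 4.8e-06, adjusted p = 0.822 with an estimated correlation). That list was chosen by name and also holds organellar ribosomal proteins. RPS8B rose by 1.51 ± 0.14, AT1G68590 fell by 0.56 ± 0.06, and RPL27C (-0.81 ± 0.08) lies in the block.

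The remaining lists were not called in tfIIfα1, with camera adjusted p from 0.0724 to 0.755. Among them, 8 of 38 nuclear photosynthesis genes rose and 13 fell, with PSAG at -0.80 ± 0.06, PSAF at -0.43 ± 0.05, PETC at 0.49 ± 0.05 and the block gene PSAL at -1.14 ± 0.06. Of 20 plastid transcription genes, 4 rose and 6 fell, with SIGA at 0.64 ± 0.06 and FSD2 at -0.81 ± 0.09. Of 7 defense genes, 3 rose and 0 fell, with the lipoxygenase gene LOX2 at 0.89 ± 0.07, and the median (-0.02) and the test (higher) differed in sign. Of 21 cell cycle genes, 3 rose and 0 fell, with PCNA at 0.56 ± 0.06, and here too the median (-0.04) and the test (higher) differed in sign. Of 14 brassinosteroid genes, 2 rose and 3 fell, with EXPA8 at -0.46 ± 0.11. Of 8 genes of seed reserve use, 1 rose, the isocitrate lyase gene ICL (1.58 ± 0.20), and the median was -0.14 with a test toward higher. Plastid genes read by the plastid's own polymerase (5 of 8), plastid-encoded genes (6 of 76) and mitochondrial genes (1 of 9) rose at low levels, such as RBCL from 9.71 ± 2.80 to 24.4 ± 12.3 CPM. Plastid-encoded genes took only 0.0145% to 0.0252% of the counts of the mRNA libraries, so these rises are a poor measure of plastid expression. In tfIIfα2, in total RNA, the same 8 plastid-polymerase genes had a median of 0.09, with 0 passing in edgeR. The median of the mitochondrial genes was -0.07, with a test toward higher. No member of the root marker, heat shock or nuclear-polymerase plastid lists passed in edgeR.

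The second comparison asked the same of tfIIfα2 against wild type in the total RNA libraries. Of 12 mitochondrial stress genes 3 rose in tfIIfα2, with NDA1 1.76-fold, the transcription factor gene NAC13 1.91-fold and the alternative oxidase gene AOX1A 1.81-fold higher. AOX1A was almost unchanged in tfIIfα1, with a log2 fold change of 0.02 in the authors' deposited table, against 0.68 for NAC13. NRPB1 was 2.13-fold and TFIIB1 1.98-fold higher, and LHY 6.01-fold. APRR3 was 13.6-fold and ADO3 9.93-fold lower. PPR genes had a median log2 fold change of -0.28. Of 18863 genes tested, 603 changed, 279 higher and 324 lower, and 132 of the higher and 103 of the lower ones changed at least 2-fold. With the replicate number as a block, 3535 changed, 1803 higher and 1732 lower, and all 603 were among them.

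Among the 8 largest rises in tfIIfα2, AT5G60250, a RING finger gene, rose 17.1-fold and SEC31A by 3.54 ± 0.57 (log2, SE). ICL, of the glyoxylate cycle, rose by 3.31 ± 0.29 from 1.25 ± 0.526 to 12.6 ± 1.86 CPM (SD, n = 3), and AT1G17960, a threonyl-tRNA synthetase gene, by 2.91 ± 0.25. JAL41 rose by 2.68 ± 0.53, AT2G18193 by 2.62 ± 0.53, and the early light-induced genes ELIP1 and ELIP2 by 2.65 ± 0.50 and 2.61 ± 0.42. ELIP1 and ELIP2 are close paralogs, so the split of reads between them is uncertain. Among the 8 largest falls, APRR3 fell by 3.77 ± 0.22 and ADO3, a blue-light receptor gene of the clock's output, by 3.31 ± 0.63. AT5G23240 fell by 2.80 ± 0.37, AT1G07050 by 2.73 ± 0.47, AT1G31690 by 2.30 ± 0.46 and AT2G29300 by 2.05 ± 0.19. The DnaJ gene AT1G56300 fell by 1.95 ± 0.32 and AT4G32340 by 1.92 ± 0.27. All of these genes had an adjusted p of 0.045 or less in edgeR, and their mutant and wild-type libraries did not overlap.

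PPR genes were lower in tfIIfα2 as a list, while few passed one by one. Of 241 tested, 7 fell and 0 rose (9 and 0 adjusted over the list alone), and with the replicate block 37 fell and 1 rose. The list's camera adjusted p was 3.4e-08, and adjusted p = 0.468 with an estimated correlation. As in tfIIfα1, the study may have chosen PPR genes on these samples, so this is not taken as independent evidence. AT5G18475 fell by 1.17 ± 0.19, AT5G02860 by 0.79 ± 0.15, AT5G24060 by 0.71 ± 0.11 and PCMP-H8 by 0.60 ± 0.11. The 28 PPR genes for mitochondrial editing had a median of -0.46 (camera adjusted p = 0.000306, adjusted p = 0.468 with an estimated correlation), and 0 of them passed in edgeR, against 2 lower with the block. PCMP-E88 was at -0.88 ± 0.24 (adjusted p = 0.086, and 0.031 with the block). Of 19 PPR genes for plastid editing, 2 fell and 0 rose (camera adjusted p = 0.013, adjusted p = 0.626 with an estimated correlation), and with the block 4 fell and 1 rose. PCMP-A2 fell by 0.70 ± 0.14 and PCMP-H81 by 0.64 ± 0.13.

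Genes of mitochondrial stress rose in tfIIfα2, 3 of 12 (9 adjusted over the list alone, 7 with the block), with 0 lower (camera adjusted p = 2.1e-08, adjusted p = 0.339 with an estimated correlation). NDA1 rose by 0.81 ± 0.10, NAC13 by 0.94 ± 0.15 and AOX1A by 0.86 ± 0.14. HSP23.5 was at 2.63 ± 0.57 (adjusted p = 0.053, and 0.0016 with the block). Of 109 mitochondrial genes, 2 rose, 18 with the block, and 0 fell (camera adjusted p = 6.3e-05, adjusted p = 0.431 with an estimated correlation), with ORF145C at 0.62 ± 0.11 and ORF117 at 0.61 ± 0.11. Of 15 basal transcription genes, 3 rose, 5 with the block, and 0 fell (camera adjusted p = 0.000159, adjusted p = 0.431 with an estimated correlation), with NRPB1 at 1.09 ± 0.09, TFIIB1 at 0.98 ± 0.11 and NRPB2 at 0.51 ± 0.10. Of 13 DNA damage genes, 2 rose, 4 with the block, and 0 fell (camera adjusted p = 0.0015, adjusted p = 0.468 with an estimated correlation), with anac044 at 2.44 ± 0.33 and GMI1 at 1.23 ± 0.13. Of 20 plastid transcription genes, 3 fell and 0 rose (camera adjusted p = 0.0045, adjusted p = 0.625 with an estimated correlation), and with the block 9 fell and 1 rose. PTAC3 fell by 0.66 ± 0.10, PTAC6 by 0.48 ± 0.10 and the sigma factor gene SIGC by 0.47 ± 0.10.

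The smaller lists called in tfIIfα2 were all toward higher. The 10 flavonoid genes had a median of 0.98 (camera adjusted p = 0.00078, adjusted p = 0.540 with an estimated correlation), with 0 passing in edgeR and 5 higher with the block. CHS was at 1.72 ± 0.37 (adjusted p = 0.053, and 0.0055 with the block). Of 5 genes of seed reserve use, 1 rose, ICL, and 2 with the block (camera adjusted p = 0.0013, adjusted p = 0.431 with an estimated correlation). Of 6 defense genes, 1 rose, VSP1 (2.59 ± 0.41), and 3 with the block (camera adjusted p = 0.040, adjusted p = 0.431 with an estimated correlation). The 4 root markers had 0 passing in edgeR and 2 higher with the block (camera adjusted p = 0.0263, adjusted p = 0.431 with an estimated correlation). CASP1, of the root endodermis, was at 2.05 ± 0.77 (adjusted p = 0.17, and 0.043 with the block). The median of the root markers was 0.54, beside the other groups toward higher in tfIIfα2.

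The other lists were not called in tfIIfα2, with camera adjusted p from 0.0754 to 0.876. Nuclear photosynthesis genes were called lower with the block alone (adjusted p = 0.0452, median -0.21, and adjusted p = 0.892 with an estimated correlation), with 6 of 38 lower. Of 11 clock genes, 3 rose and 3 fell, and with the block 4 rose and 7 fell. LHY rose by 2.59 ± 0.13 and CCA1 by 0.94 ± 0.11, and ADO3 and ELF3 (-0.80 ± 0.15) fell. The median of this list was -0.80 and its mean -0.30, while its test pointed toward higher (adjusted p = 0.638) and, with the block, toward lower (adjusted p = 0.0598), passing in neither. Of 348 ribosomal protein genes, 1 rose, RPL39B (0.77 ± 0.14), and 2 fell, AT1G68590 (-0.53 ± 0.10) and AT1G24240 (-0.80 ± 0.16), and with the block 22 rose and 8 fell. In the chlorophyll synthesis, reactive oxygen, brassinosteroid, cell cycle, non-PPR editing, heat shock, topoisomerase VI and the plastid-encoded, plastid-polymerase and nuclear-polymerase plastid lists, 0 genes passed in edgeR. With the block, 5 plastid-encoded genes rose and 4 fell, 3 brassinosteroid genes rose, 2 chlorophyll genes rose and 1 fell, 1 cell cycle gene rose and 2 fell, 1 non-PPR editing gene rose and 2 fell, and 1 reactive oxygen gene rose and 1 fell. PORA was at 3.21 ± 0.73 (adjusted p = 0.061, and 0.00026 with the block), and TOP6A, TOP6B, RHL1 and BIN4 lay between -0.14 and 0.23.

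Removing 1 library left 4 to 169 genes in tfIIfα2: 169, 4 and 26 without wild-type replicate 1, 2 or 3, and 37, 8 and 125 without tfIIfα2 replicate 1, 2 or 3. DESeq2 called 1294.

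**Figure D3:**
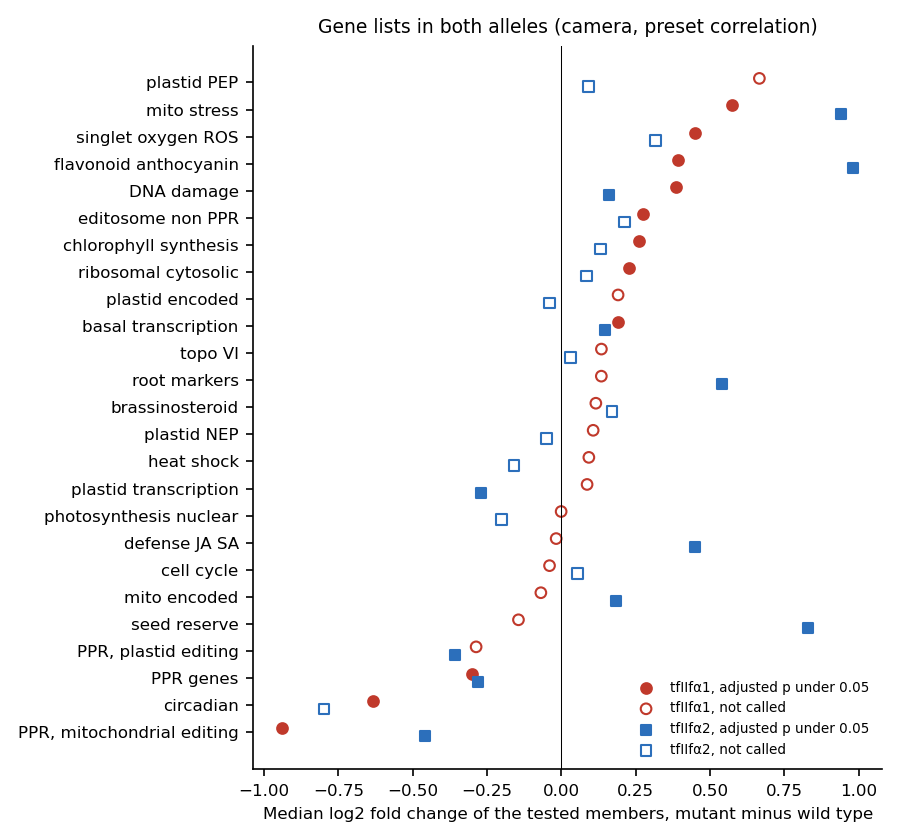
Median log2 fold change (mutant minus wild type) of the tested members of each list in tfIIfα1 (circles) and tfIIfα2 (squares); filled symbols had a camera adjusted p under 0.05 with the preset correlation, and no list did with an estimated correlation. PPR genes for mitochondrial editing had medians of -0.94 and -0.46, and mitochondrial stress genes 0.57 and 0.94.

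The third comparison asked whether both alleles changed the same genes. SEC31A, AT5G60250 and AT1G17960 were among the genes with the largest rise in both, and APRR3, BGLU43 and AT5G23240 among those with the largest fall. NRPB1, TFIIB1, NRPB2, LHY, CCA1, NDA1, anac044 and GMI1 were higher in both, and ADO3 and ELF3 lower in both. Of 18477 genes tested in both, 237 were higher in both, against 54.1 for independent lists, and 299 lower in both, against 66.7 (Fisher's exact test, one-sided, p = 3.3e-128 and 7.4e-176). A further 6 genes changed in opposite directions. Genes are not independent replicates, so these p-values describe the overlap alone. With the replicate block, 2589 genes changed in the same direction and 30 in opposite ones, and with 1 total RNA library left out, 4 to 159 changed in the same direction.

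The 6 largest shared rises also held PDC4, a pyruvate decarboxylase gene (2.76 ± 0.37 in tfIIfα1, 2.73 ± 0.57 in tfIIfα2), HVA22G (2.67 ± 0.40, 2.64 ± 0.46) and AT5G53230 (2.76 ± 0.46, 3.54 ± 0.43). The 6 largest shared falls also held AT3G23480 (-2.48 ± 0.20, -2.58 ± 0.47), AT1G43675, a transposable element gene (-2.14 ± 0.39, -2.55 ± 0.48), and ADO3. Across the 18477 genes the log2 fold changes had Pearson's r = 0.68 and Spearman's rho = 0.67, a description across genes. The alleles had separate wild-type libraries. Of 596 genes called in tfIIfα2 and tested in both, 586 (98.3%) had the same sign in tfIIfα1.

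**Figure D4:**
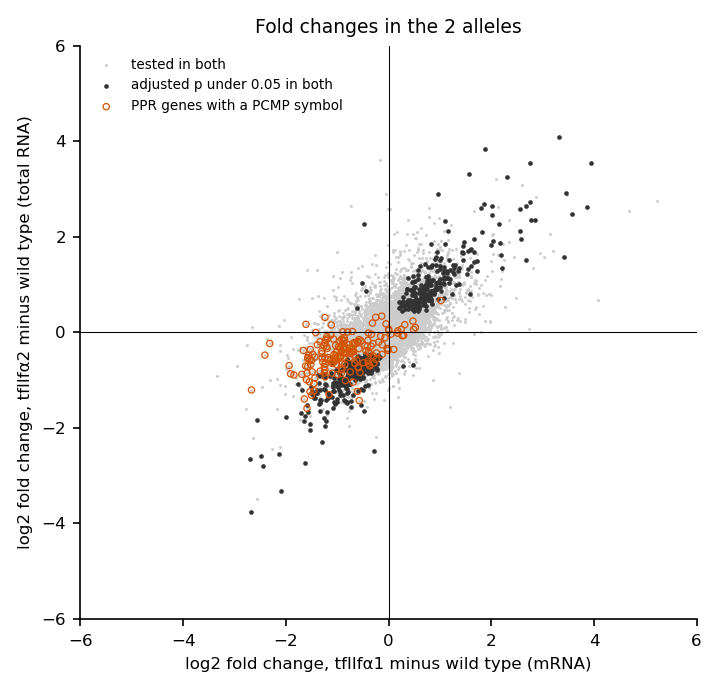
Log2 fold change of each gene in tfIIfα1 (horizontal axis, mRNA libraries) and tfIIfα2 (vertical axis, total RNA libraries) for 18477 genes. Dark points passed an adjusted p under 0.05 in both, 536 with the same sign and 6 with opposite signs, and open circles are PPR genes with a PCMP symbol.

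The fourth comparison tested the difference between the alleles' changes. The 4 genes with the smallest p, PAT19, AT4G12780, AT4G15545 and SMAP1, lie in the chromosome 4 block. Of 20602 genes tested, 159 differed, 147 toward higher and 12 toward lower in tfIIfα2, and 123 of them lie in the block and 36 elsewhere. This fit gave each gene 1 spread for both kits. The kits' own coefficients of variation were 0.0827 (mRNA) and 0.184 (total RNA), so calls and errors here rest on a shared spread that may hold for neither. PAT19 was at -1.29 ± 0.06 in tfIIfα1 and -0.11 ± 0.09 in tfIIfα2. With the block genes left out of the fit, 5 differed: AT4G05631 (difference -1.16 ± 0.13), AT1G53900 (1.18 ± 0.14), APA2 (1.49 ± 0.17), AT5G03350 (1.60 ± 0.20) and the lipid transfer gene LTP2 (2.75 ± 0.35). These 5 were chosen after their values were seen. With the replicate number as a block, 415 differed, and the larger part lay elsewhere, 238 against 177 in the chromosome 4 block.

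Genes that overlap others or have an antisense partner are uncertain throughout, since the strand setting of the counting is not given.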

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

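Tests of regulation by TFIIFα and of normalization for the chromosome 4 block, of harvest time for the clock genes, and of the protein class of PPR genes were chosen only after the results were seen.

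By a test of the difference itself, which cannot tell the allele from the kit or its wild type, the changes differed for 159 genes. Of these, 123 lie in the chromosome 4 block, whose offset lay in the wild-type mRNA libraries. With the block genes left out of the fit, 5 differed. The largest evidence was for PAT19 (1.17, tfIIfα2 minus tfIIfα1, log2), AT4G12780 (1.13), AT4G15545 (1.27) and SMAP1 (1.18), all in the chromosome 4 block. Of 100 drawn pairs of splits of the libraries, 8 gave as many genes, the real one included, with a highest other of 6705. The 7 other draws all kept the real split of the mRNA libraries, and the highest was the real split of both kits with the total RNA labels reversed. These draws point to a structure of the samples, since they carry the real mRNA difference, so they do not decide whether chance gives 159 genes.

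The chromosome 4 block was about 1 log2 unit lower in tfIIfα1, beginning next to RAP74. A lower dose in tfIIfα1 is argued against by its offset of -0.0135 against tfIIfα2 across kits, regulation by TFIIFα by the median of -0.0315 in tfIIfα2, and normalization or library size by the neighbours, whose lower median was -0.0053. The wild-type mRNA libraries stood 0.98 above the wild-type total RNA libraries in the block, so extra copies of the block in that wild-type line are a candidate explanation. The sample titles name the wild types of the kits differently (1171WTCol3 for mRNA, WTCol0 for total RNA) without saying how they differ, and no DNA was sequenced, so copy number itself was not measured.

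PPR genes were lower in both alleles as a list at the preset correlation, but not with an estimated one (adjusted p = 0.251 and 0.468). Non-PPR genes matched on length, exon number, GC content and expression lay above them. The median difference was -0.32 in tfIIfα1 and -0.34 in tfIIfα2 (PPR minus matched), which argues against these properties as the whole cause. The permutation p was 1e-04 in both, the smallest the permutations can give. It treats genes as independent, so it does not measure the spread between samples. Members inside the chromosome 4 block do not account for it, since 42.5% of the listed PPR genes outside it fell in tfIIfα1. Of the genes outside both the block and the list, 18.5% fell, and these include PCMP genes that the list leaves out. The choice of the list by the study and a harvest at another time stay open, and no biological explanation beyond the genotype was tested.

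Of the 12 listed clock genes, 10 were given a morning or evening side after the results were seen. AT5G02810 and ELF3, which also fell in tfIIfα1, were left out. For the 10 chosen, the signs followed the assigned side for 10 of 10 in tfIIfα1, all of which passed. In tfIIfα2 they did so for 9 of the 9 tested, of which 5 passed. Since the genes were chosen after their values were seen, these counts are no test of phase. Harvest at another time of day and an effect of the mutations on the clock cannot be told apart, since the labels give no harvest time. The smaller count of signs, 9, does not decide between them.

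For the genes changed in tfIIfα1 and in tfIIfα2, 1 of 10 splits of the 6 libraries gave as many (7820 and 603, highest other 0 in each); with 10 splits the share cannot be under 0.05. For the lists, 2 of 10 splits gave as many in each allele (11 and 12, highest other 11 and 12), and the splits are again too few; every mixed split called 0 genes but still 4 to 11 lists in tfIIfα1 and 5 to 12 in tfIIfα2 at the preset correlation. Of the 4 splits of the total RNA libraries that part 3 pairs, the real one called 603 genes and the others at most 0. For genes changed in the same direction, 1 of 100 drawn pairs of splits gave as many (536, highest other 6). Every other split of either kit called 0 genes, so a pair with a mixed split could not share any, and these draws decide no more than the splits of each kit.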

How the results depend on the processing

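Halved or thinned mRNA counts, removal of the chromosome 4 block and the PCMP list were chosen after the data were seen. RLE normalization and removal of organelle genes kept each count of genes and lists within 1.5 times its value. So did a minimum of 1 CPM for the 4 counts of genes, and no filter and limma-voom for the counts of each allele, the results they were run for. Both PPR lists kept their direction under every alternative run for them. In tfIIfα1, 5137 genes passed an adjusted p of 0.01, 1069 passed at 0.05 with at least 2-fold, and 4329 in 1 fit over 12 libraries. In tfIIfα2 the counts were 28, 235 and 2926, and DESeq2 called 1294. With the replicate block, 3535 genes changed in tfIIfα2, 2589 in the same direction in both alleles, and 415 differed between alleles. The block changed the calls of 43 genes named in tfIIfα2, RAP74 among them, all toward called, and 1 list, nuclear photosynthesis; of the lists and the genes named in tfIIfα2 it changed no other call. In tfIIfα1 no paired analysis was run because the replicate numbers of 2 of its 3 columns are ambiguous. At an adjusted p of 0.01, 28 genes changed in the same direction. The correlation between alleles was 0.72 with at least 1 CPM in 3 libraries. Without the block genes, 5 genes differed between alleles, fewer than the 36 of the 159 that lie outside it. With an estimated correlation, 0 lists were called in either allele, and the PPR lists (medians -0.30 and -0.28) had adjusted p = 0.251 and 0.468. Against matched random lists the clock list in tfIIfα2 (median -0.80) was called lower, the reverse of its test. They ended the calls of chlorophyll synthesis in tfIIfα1 (adjusted p = 0.325) and of basal transcription (0.118), DNA damage, defense and root markers (0.0914 each) in tfIIfα2. They added 4 calls in tfIIfα1, and 4 in tfIIfα2 besides the clock list. Stricter thresholds lower counts by construction; for the rest the cause was not tested.

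With 1 library left out, the ranges were 6351 to 7039 genes in tfIIfα1, 4 to 169 in tfIIfα2, 4 to 524 in the same direction, 108 to 146 between alleles, 0.60 to 0.67 for the correlation, 10 to 12 and 10 to 14 lists, and -0.31 to -0.22 and -0.33 to -0.21 for the PPR medians. The same-direction count fell to 159, 4 and 26 without wild-type total RNA replicate 1, 2 or 3, and to 37, 8 and 116 without tfIIfα2 replicate 1, 2 or 3; the tfIIfα2 count fell to 169, 4, 26, 37, 8 and 125 in the same order. Fewer samples can lower such counts. The tfIIfα1 comparison kept at least 6351 of its 7820 genes, but its biological coefficient of variation was smaller (0.0827 against 0.184). At the same number of libraries, the tfIIfα2 and same-direction counts varied widely with the library left out. Every removal of a total RNA library cut both to 169 or fewer, in fits without the replicate block. With all libraries, 28 of the 603 genes in tfIIfα2 passed an adjusted p of 0.01 in edgeR. Most calls thus lay near the threshold, and the counts do not single out a library. Thinned to the nuclear depth of the total RNA libraries, the mRNA libraries gave 5814 genes in tfIIfα1. Simulated 1.5-fold changes were recovered at 10.4% in the tfIIfα2 and 72.7% in the tfIIfα1 comparison. The replicate block raised the tfIIfα2 count to 3535. The lower count therefore does not show a weaker effect of tfIIfα2, and how much each of these contributes was not tested.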

Other observations

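The protein class of the PPR genes was tested only after the results were seen.

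PPR genes with a PCMP symbol, a name given mostly to PPR proteins with E or DYW domains, were lower than the others. In tfIIfα1, 134 of 180 fell and 6 rose, with a median of -0.90, among them PCMP-H43 and PCMP-E9. In tfIIfα2, 7 of 173 fell and 0 rose, with a median of -0.42. Outside the chromosome 4 block, the listed PPR genes with such a symbol had a median of -0.90 over 80 genes, against -0.05 over 160 other PPR genes. In tfIIfα2 the medians were -0.44 and -0.22, a difference of -0.22 (permutation p = 6e-05, two-sided, across genes, which treats genes as independent). With an estimated correlation the PCMP list had an unadjusted camera p of 0.0068 in tfIIfα1 and 0.108 in tfIIfα2. Listed PPR genes without the symbol and in neither editing list were lower in tfIIfα2 too, with a median of -0.22 over 156 genes. Their unadjusted camera p there was 1.2e-06 at the preset correlation and 0.253 with an estimated one. In tfIIfα1 these values were 0.172 and 0.424. The decrease may follow this protein class more than PPR genes as a whole in tfIIfα1, while in tfIIfα2 other PPR genes were lower as well. PCMP genes were lower expressed (median log2 CPM 0.97 against 2.27 in the mRNA and -0.07 against 1.59 in the total RNA libraries). The 2 sets were not matched on expression.

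A test that halved the mRNA counts was withdrawn as a test of read pairs counted separately after its result was seen, because halving changes every gene and mRNA library by one factor. Halved counts remain as a processing alternative, where 7813 genes changed in tfIIfα1.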
